A study of Rattus norvegicus with 4 samples.

How the data were processed

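Gene expression in the fracture callus of rats was measured on 4 single-colour microarrays, 1 for each combination of condition (control or diabetic) and day (5 or 11). Per the labels' protocols, callus tissue of 5 animals was pooled for each array, RNA was amplified to amino allyl aRNA and coupled to Cy5. Diabetes was induced with 40 mg/kg streptozotocin, a toxin of the insulin-producing beta cells, and the diabetic animals had blood glucose over 300 mg/dl. Because each group is 1 array of pooled RNA, the spread between animals was averaged out before the measurement and cannot be estimated.

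The deposited array files hold, per the file headers, the median foreground intensity of each spot at 635 nm, a local background intensity and a quality flag at each of 3 scanner gains. How the gains were combined into a value, the scanner, its software and the genome annotation behind the probes are not given in the sources used here. Each array carries 27456 spots, of which 20174 are gene probes with 20174 distinct Ensembl gene IDs. The other spots are blank spots, spots marked as having no probe, negative and positive controls and QC probes. The authors also deposited a table of processed intensity values on a linear scale, with a null for dim genes. Set against the spot medians, each column of that table lay on a straight line: the value was the spot median minus the blank-spot mean of the array, times 1 factor per array that gave the listed genes a median of 25. A gene was null where its spot did not exceed the mean plus 2 SD of the blank spots after 5% trimming at each end, or where a gain flag was bad. Only 1 listed gene on the day 5 control array and 9 on the day 11 control array lay just under the limit as recomputed.

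Neither the files nor the tables used here pair the Ensembl IDs with gene symbols: 0 of the 20174 IDs matched among the 47357 genes of the reference table, which lists no Ensembl IDs. The 27 gene lists (cartilage, bone, osteoclast, vessel, immune, muscle and other markers) that had been fixed beforehand were therefore not applied, and no cell type or pathway is reported. At most 2 IDs are printed for each direction.

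Spot medians were corrected for background with limma 3.58.1 in R 4.3.3 (normexp, offset 50), with the blank-spot mean of each array as background. Control spots were then left out, together with 13 gene probes with a bad flag on any array, which left 20161 genes. The arrays were quantile normalized and log2 values taken. The blank-spot level was preferred to the local background column after the files were read and before groups were compared, since the local background rose with the signal of its own spot (r of the log values 0.981 to 0.99 across arrays). The offset of 50 exceeds the median net signal of the genes above background (35.67 to 49 per array), so every fold given is on the intensity + 50 scale and understates the change of dim genes.

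A gene entered a comparison of 2 arrays if it was above the blank-spot limit on at least 1 of them. With 1 array per group there was no replicate error, so genes were described by size, as at least 2-fold apart (a log2 difference of 1), without a p-value. An additive model over all 4 arrays (day plus condition, limma lmFit and eBayes) left 1 residual degree of freedom per gene. It tested the diabetes effect averaged over both days and the day effect averaged over both conditions, with Benjamini-Hochberg adjusted p under 0.05. Its error term is the change of the diabetes effect between the days, so it holds real differences between days as well as noise. A second limma fit tested that change itself, with the day effect as its error term, and also left 1 residual degree of freedom per gene. In data simulated for the averaged diabetes comparison (14682 genes, equal noise SD of 0.205), the additive fit recovered 46 of 50 genes changed by 1 on the log2 scale and all 50 changed by 2. With noise that varied between genes as in the real fit, it recovered 0 of 50 genes changed by 1, and of those changed by 2, 3 and 4 it recovered 40, 45 and 42 of 50. Unchanged genes called by the fit numbered 10 with equal and 13 with varying noise. The lowest adjusted p in limma was 0.0174 in the simulation with varying noise but 0.275 for diabetes in the real data. The simulated recoveries therefore cannot be carried over to the real fit, and a lack of calls there does not exclude large changes.

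IDs to be named followed a rule fixed before the data were examined, which also required a gene symbol. That requirement could not be met and was dropped, as were the parts on gene list members and on genes above the limit on 1 array only. The remaining rule took genes above the limit on both arrays, brighter than the median of such genes and with the same direction in the authors' table, ranked by log2 difference. Printing only the first of each list was settled once the lack of symbols was known. The 8 highest and 8 lowest per comparison are summarised, and the first of each list is named for the comparisons of diabetic with control callus. Alternatives covered the authors' table, other background corrections, offsets, scalings, filters and fold thresholds. Bootstrap intervals came from 1000 resamples of genes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.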

Results

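Fracture callus, the repair tissue that forms around a broken bone, was collected from control and streptozotocin-diabetic male rats on day 5 and day 11 after a closed fracture of the femoral shaft. The diabetic animals served as a model of impaired fracture repair. Material from 5 animals per group was pooled and its RNA hybridised to 1 array, giving 4 arrays in all. None of the pairwise differences between arrays has a replicate check. Between 15846 and 16377 of 20161 genes were above the blank-spot limit on each array. That was 81.2% of genes in control and 79.6% in diabetic callus on day 5, and 78.6% and 79.1% on day 11. The precision is limited by the number of arrays. Repeats of 1 positive control probe within an array, at 24 spots each, had a coefficient of variation of 7.98% to 11.8%, and those of the other positive control probe, also at 24 spots, of 16.9% to 28.8%. These cover spot-to-spot error only. Spots without a gene probe give the background measured in the same way: 6.85% to 7.64% of blank spots and 49.0% to 69.8% of negative control spots were above the limit.

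**Figure D1:**
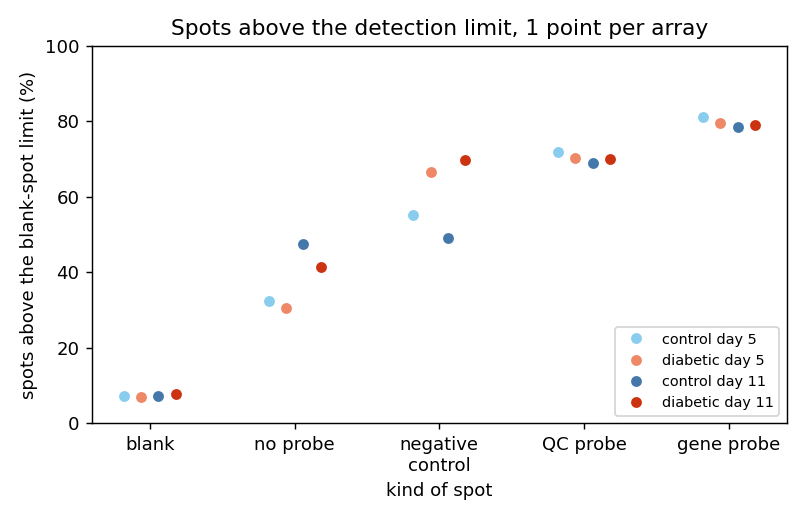
Percent of spots above the blank-spot detection limit (vertical axis) by kind of spot, with 1 point per array. Negative control spots lie between 49.0% and 69.8%, far above the blank spots at about 7% and below the gene probes at 78.6% to 81.2%.

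The first question was which genes differ between diabetic and control callus in the early repair phase. On day 5, 256 of 17030 genes (1.5%) were at least 2-fold apart, of which 91 were higher and 165 lower in diabetic callus. At least 4-fold differences were found for 43 genes, 11 higher and 32 lower. With the offset used, 95.3% of genes were within 1.5-fold. The offset raises this share for dim genes, so it does not show that most of the transcriptome was equal. ENSRNOG00000022282 had the largest positive difference among the brighter genes, 43.3-fold higher in diabetic callus, with a net signal of 246.2 in control and 11940 in diabetic callus. ENSRNOG00000011483 had the largest negative difference, 34.3-fold lower, with a net signal of 8129 in control and 161.3 in diabetic callus. The 8 leading higher genes had log2 differences of 2.15 to 5.44, and the 8 leading lower genes of -3.27 to -5.10. A further 1627 genes were above the limit on only 1 of the 2 day 5 arrays, and 1 of these was at least 2-fold lower in diabetic callus with its dim value set to the lowest signal among genes above the limit. In the authors' deposited table, which carries no offset, 497 genes were at least 2-fold higher and 794 lower on day 5. The excess of lower genes depends on the background used, since normexp with the local background column gave 362 higher and 261 lower genes.

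On day 11 the difference between diabetic and control callus covered more genes. At least 2-fold differences were found for 714 of 16732 genes (4.27%), 362 higher and 352 lower in diabetic callus, and 170 genes were at least 4-fold apart, 87 higher and 83 lower. On the intensity + 50 scale the share of genes within 1.5-fold was 89.6%, again raised by the offset for dim genes. ENSRNOG00000000545 led the higher genes at 170-fold, with net signals of 14.84 in control and 11030 in diabetic callus. On day 5 this gene was 8.89-fold higher in diabetic callus. Its control signals lie near background, so the background correction and offset govern its folds. In the authors' deposited table its log2 differences were 5.97 on day 5 and 9.77 on day 11, against 3.15 and 7.41 here. When normexp used the local background column they were 0.86, under 2-fold, and 5.37. ENSRNOG00000011483 again led the lower genes, at 46.0-fold lower in diabetic callus, with net signals of 8440 and 124.4. ENSRNOG00000022282 was 50.3-fold higher on day 11. The 8 leading higher genes had log2 differences of 5.58 to 7.41 and the 8 leading lower genes of -3.81 to -5.52. Among genes above the limit on 1 array only, 6 were at least 2-fold higher and 3 at least 2-fold lower in diabetic callus by their lower bound. On day 11 the authors' deposited table gave at least 2-fold differences for 1211 genes higher and 1083 genes lower.

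**Figure D2:**
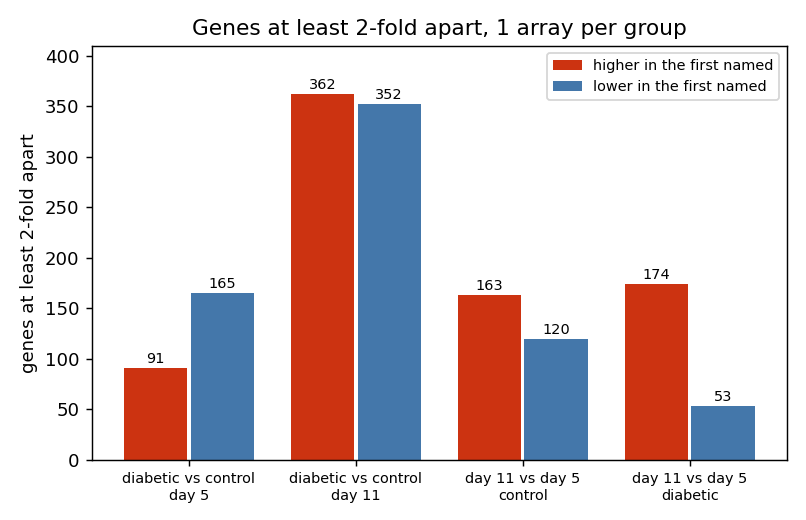
Number of genes (vertical axis) at least 2-fold apart in each of the 4 comparisons of 2 arrays, with genes higher in the first-named array in red and lower in blue. The largest counts, 362 higher and 352 lower, belong to diabetic against control callus on day 11.

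The arrays of the 2 days are separate pools, which allows the diabetes effect to be compared between days. Over 16101 genes, the diabetic minus control log2 differences of day 5 and day 11 had a Pearson r of 0.595 and a Spearman rho of 0.51. These are correlations across genes, which are not independent replicates. At least 2-fold differences in the same direction on both days were found for 147 genes. The 59 higher on both days compare with 2.05 expected for independent lists, and the 88 lower on both days with 3.6. These expectations take no account of signal and are too low. The brightest of 4 equal bins of signal held 161 calls of day 5 and 381 of day 11, and the dimmest 0. Opposite directions past 2-fold were found for 5 genes, against 5.69 expected in the same way. The count was 109 genes, beside 141 in the same direction, when normexp used the local background column. No expected count was computed for that setting. Of the 11 genes at least 4-fold higher in diabetic callus on day 5, 10 were at least 2-fold higher on day 11. Of the 32 genes at least 4-fold lower on day 5, 23 were at least 2-fold lower on day 11. The 8 leading higher genes of day 5 were all at least 2-fold higher on day 11 as well, and 6 of the 8 leading lower genes were at least 2-fold lower. This agreement depends on the background used: it had an r of 0.064 when the local background column was subtracted and 0.090 when normexp used that column.

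**Figure D3:**
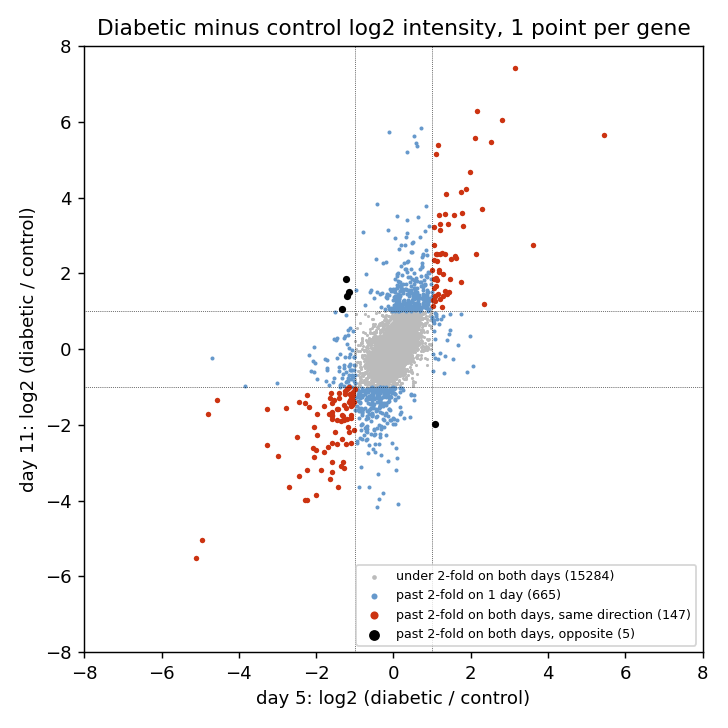
Each point is a gene; the axes give the log2 ratio of diabetic to control callus on day 5 (horizontal) and day 11 (vertical), on the intensity + 50 scale, with dotted lines at 2-fold. The 147 red points lie past 2-fold in the same direction on both days, and the 5 black points in opposite directions.

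Within this agreement the measured diabetic minus control differences were spread more widely on day 11 than on day 5. Noise of the day 11 arrays together was not excluded as the source. The SD of the log2 differences over all genes was 0.305 on day 5 and 0.485 on day 11. For 468 of 16101 genes (2.91%) the log2 difference changed by at least 1 from day 5 to day 11. For 398 of these it was larger in size on day 11, and for 70 it was smaller. A wider spread on day 11 by itself favours such a split. Of the 561 genes past 2-fold on day 11 only, 88.4% had the same direction on day 5, and of the 104 genes past 2-fold on day 5 only, 76.9% had the same direction on day 11. A limma test of this change took the day effect as its error term, which holds real differences between days. It called 0 genes, with a lowest adjusted p of 1 and 483 genes at an unadjusted p under 0.05 where chance would give 883. Over genes above the limit on all arrays, the error had a wider spread than the change tested (SD 0.249 against 0.205). Few calls could therefore arise, and their lack does not exclude changes.

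The diabetes effect averaged over both days was tested with the additive limma fit over 17661 genes. No gene had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.275. At an unadjusted p under 0.05 there were 2657 genes, 1327 higher and 1330 lower in diabetic callus, where chance would give 883. The size of this excess depends on the background used. The count was 889 with the local background subtracted and 1165 when normexp used that column. ENSRNOG00000022282 had an averaged log2 difference of 5.54 (SE 0.0809) and ENSRNOG00000011483 of -5.31 (SE 0.144), each with an adjusted p of 0.275 in limma. ENSRNOG00000000545 had an averaged log2 difference of 5.28 with a wider SE of 1.39 and an adjusted p of 0.327 in limma. With limma's trend and robust options 3 genes passed, namely ENSRNOG00000022282 and ENSRNOG00000011483 together with ENSRNOG00000011557, which had an averaged log2 difference of -4.99 and was named after its values were seen. Their adjusted p in that limma fit were 0.0234, 0.0328 and 0.0234, while the lowest adjusted p for diabetes in limma under the other alternatives was between 0.0764 and 0.761.

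The progress of the callus from day 5 to day 11 was compared within each condition. In control callus 283 of 16893 genes (1.68%) were at least 2-fold apart between the days, 163 higher and 120 lower on day 11. In diabetic callus there were 227 of 16803 genes (1.35%), 174 higher and 53 lower on day 11. These splits by direction depend on the values used, since the authors' deposited table gave 485 higher and 773 lower genes in control callus and 571 higher and 504 lower in diabetic callus. The 8 leading higher genes on day 11 in diabetic callus had log2 differences of 4.70 to 6.06, while the same genes in control callus had differences of 0.19 to 0.95. The 8 leading higher genes in control callus had differences of 2.93 to 3.97, and in diabetic callus of -0.25 to 0.34. Of the 8 leading lower genes in diabetic callus, 3 were at least 2-fold lower in control callus, and of the 8 leading lower genes in control callus, 0 were at least 2-fold lower in diabetic callus. Each set was picked for its size in 1 condition, which by itself favours smaller differences in the other. The offset also shrinks the differences of dim genes.

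The day effects of the 2 conditions were compared gene by gene. Over 16035 genes the Pearson r between the control and the diabetic day effect was 0.187 and the Spearman rho 0.236. Past 2-fold in both conditions and in the same direction were 22 genes, 9 higher and 13 lower on day 11. For independent lists, again without account of signal, 1.74 and 0.393 were expected. Opposite directions were found for 15 genes, against 1.81 expected. Of 43 genes at least 4-fold higher on day 11 in diabetic callus, 5 were at least 2-fold higher in control callus, with a median log2 difference of 0.198 there. The direction was the same in control callus for 29 of the 43. Of 31 genes at least 4-fold higher on day 11 in control callus, 3 were at least 2-fold higher in diabetic callus and 26 had the same direction there. Of 17 genes at least 4-fold lower on day 11 in control callus, 2 were at least 2-fold lower in diabetic callus and 13 had the same direction. Of only 3 genes at least 4-fold lower on day 11 in diabetic callus, 2 were at least 2-fold lower in control callus, with a median log2 difference of -1.93 there. In the additive limma fit no gene passed an adjusted p of 0.05 for the day effect averaged over conditions, with a lowest adjusted p of 0.524. At an unadjusted p under 0.05 there were 1613 genes, where chance would give 883. This count was 653 with the local background subtracted and 926 when normexp used that column.

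Averaged contrasts of condition and day were compared over all 4 arrays. Over 14682 genes above the limit on all arrays, the SD was 0.378 for the diabetes effect averaged over days, 0.249 for the day effect averaged over conditions and 0.205 for the change of the diabetes effect between days. The change was scaled so that all 3 contrasts carry the same amount of array noise if the arrays are equally noisy. At least 2-fold values were found for 403, 130 and 86 genes in the same order. The SD for diabetes was above that for day in all 9 other settings of the values, but with the local background subtracted by only 0.857 against 0.784. The order of day and change turned with the local background, at 0.784 against 0.799 when it was subtracted and 0.321 against 0.339 in normexp. Between single arrays, diabetic and control callus of day 11 were 714 genes apart at 2-fold (r 0.9504) and those of day 5 were 256 genes apart (r 0.9799). The days were 283 genes apart in control callus (r 0.9803) and 227 in diabetic callus (r 0.9804). The order of the 3 smaller counts depends on the values used: the authors' deposited table gave 1291, 1258 and 1075, and normexp with the local background 623, 552 and 854. With the local background subtracted, the diabetic day count of 5194 was above the 5117 between the conditions on day 11.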

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

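The detection limit set on negative controls was chosen after the data and the first gene counts had been seen; so were the tests of variance between arrays, the comparison band above that limit and the counts by signal bin. The predicted outcomes of the other tests were written after those counts and before the test values.

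The difference between diabetic and control callus went past 2-fold in opposite directions on day 5 and day 11 for 5 genes. With 1 array per group this difference was not tested, and it is no more than the 5.69 genes expected for independent lists. The count was 28 in the authors' table, 136 with the blank level subtracted and 638 with the local background subtracted. The lists of genes past 2-fold were much longer at these settings. The number expected for independent lists was not computed for them, so these counts do not show an excess.

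Spots that carry no gene probe were not part of any comparison, and many gave signal above the blank-spot limit, which only 6.85% to 7.64% of blank spots exceeded. Among the 809 spots marked as having no probe the share above it was 32.3% in control and 30.4% in diabetic callus on day 5, and 47.6% and 41.5% on day 11. Among the 96 negative control spots it was 55.2% and 66.7% on day 5, and 49.0% and 69.8% on day 11. The 521 QC probes exceeded the limit in 71.8% and 70.2% of spots on day 5, and in 69.1% and 70.1% on day 11. The diabetic minus control log2 differences of the QC probes correlated between the days with an r of 0.475 over spots, against 0.59 over genes on the same uncorrected signals.

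A candidate explanation for the negative control signal is unspecific binding that a limit set on blank spots does not take into account, so that genes just above the limit are not measured usefully. For 637 genes between the blank-spot limit and the negative control limit on all 4 arrays, the diabetes effects of the days correlated with an r of 0.0878. This does not decide it, since 164 genes that stayed in an equally wide band just above gave an r of -0.0809. A low r is thus not particular to genes between the limits. Whether the narrow band or the dim signal lowers the correlation was not tested. A limit at the mean plus 2 SD of the negative controls left 13190 to 13811 genes per array in place of 15846 to 16377. The nature of the negative control sequences stays unknown.

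More genes were past 2-fold between diabetic and control callus on day 11 than on day 5. Independent noise of 1 day 11 array alone was argued against: the variance of the diabetes log2 difference was higher on day 11 by 0.157 (bootstrap 95% interval over genes 0.136 to 0.179), above the whole variance between the days in control (0.105) and diabetic callus (0.104), of which that noise is part. Noise of both day 11 arrays together stays open, since those variances sum to 0.209, and the 88.4% of 561 genes past 2-fold on day 11 only with the same direction on day 5 does not exclude it: effects common to both days raise that share, which was 76.9% for the 104 genes past 2-fold on day 5 only. A lower sensitivity of the day 5 arrays stays open too. Among 7340 brighter genes the counts were 627 on day 11 and 237 on day 5, a ratio of 2.65. These hold nearly all counted genes. In 3 of 4 equal bins of signal, from bright to dim, the counts were 381 and 161, 246 and 76, and 75 and 16. The excess was thus relatively larger among dimmer genes. The bins cannot decide the question, since the offset raises the fold that a dim gene must reach. Over all genes the excess was likewise relatively larger at 3-fold (293 and 77) than at 1.5-fold (1746 and 798). A wider gap between diabetic and control callus on day 11 is the biological reading and stays an untested hypothesis, since each pool was measured once and the make-up of the pools (tissue collected, cell types, single animals) could not be examined without gene names.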

How the results depend on the processing

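Normexp with the local background and the negative control limit were chosen after seeing the data, including the first gene counts; the other alternatives were set beforehand, and the predictions for the tests below were written after the counts and before the test values. Counts are for day 5 diabetes, day 11 diabetes, control day effect and diabetic day effect, in order. With the authors' table they were 1291, 2294, 1258 and 1075, with the blank level subtracted without offset 2182, 3291, 2126 and 2007, and with offset 16 they were 408, 1146, 471 and 360. Subtracting the local background gave 4268, 5117, 3851 and 5194, and normexp with it 623, 1012, 552 and 854. A 1.5-fold threshold gave 798, 1746, 880 and 672, and a 3-fold threshold 77, 293, 90 and 74. Genes past 2-fold between diabetic and control callus in the same direction on both days, 147 as reported, numbered 670, 853 and 249 with the authors' table, blank subtraction and offset 16, 869 with local subtraction, and 499 and 46 at the other thresholds. Genes whose diabetes effect changed by 2-fold between days, 468 as reported, numbered 1824, 2670 and 744, then 6688 with local subtraction and 1476 with local normexp. The correlation of the diabetes effects of the days was 0.452 with blank subtraction, 0.064 with local subtraction and 0.090 with local normexp, and between 0.571 and 0.600 in the other settings. Limma called 0 genes for diabetes in every setting but trend and robust, which called 3, and 0 for day in all. No background correction, median, percentile and loess scaling, and the filters on dim probes kept every count within 1.5 times, though no filter and the negative control limit only affect genes that the offset keeps under 2-fold in the pair counts. Of the main calls, 249 of 256 and 697 of 714 were also called in the authors' table, but under local normexp only 112 and 322. Median scaling shifted all genes by 0.102 on day 5 and percentile scaling by 0.111, the authors' table by -0.142 and -0.109 for the day effects, and blank subtraction by -0.101 for the control day effect. More genes differed on day 11 than on day 5 in every setting. Of 72 alternative values of the 3 IDs named by rule, 71 stayed on their side of 2-fold and 0 reversed; ENSRNOG00000000545 on day 5 had a log2 difference of 0.86 under local normexp.

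The cause of the loss of agreement under the local background was not settled. That column's own log2 differences correlated between the days with an r of 0.302 (bootstrap 95% interval 0.269 to 0.333), and it was 59.5% to 71.9% of spots above 1000. Spots without probe or with negative controls (905) gave an r of -0.0989, and removing block and row means left 0.602 over genes, against position as the source of the agreement. An effect that scales with signal stays open, since the QC probes gave an r of 0.475.

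No paired analysis was possible because the labels give no replicate numbers; the additive fit compared the conditions within each day. Leaving out an array leaves no test. The gene list medians were not run for want of gene names, nor was the choice of the brightest probe, since each ID has 1 probe, nor a slide block, since the files show no slide with over 1 array. The offset of 50 keeps dim genes under 2-fold (median net signal 6.2 in the dimmest of 4 equal bins), so the counts say nothing of them.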

Other observations

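Both tests in this part were chosen after the results they measure had been seen.

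Diabetic callus of day 11 differed 2-fold from control callus of day 5 in 452 genes, fewer than the 714 that separated it from control callus of day 11. Diabetic callus of day 5 differed from control callus of day 11 in 668 genes, against 256 from control callus of day 5. Of 87 genes at least 4-fold higher in diabetic callus on day 11, 80 were also higher on day 5, with a median log2 difference of 0.841, and of 83 genes at least 4-fold lower, 79 were also lower, with a median of -0.828.

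A hypothesis for this order is delayed progress, in which diabetic callus of day 11 still resembles an earlier control stage. The count of 452 against 714 goes with it. Other counts show no approach of diabetic callus to the control stages between the days. Its distance from control callus of day 11 was 668 genes on day 5 and 714 on day 11, where progress towards that stage would lower it. From control callus of day 5 it was 256 and then 452 genes apart. Noise of the diabetic day 11 array could raise both later counts. Noise of the day 11 control array would raise the counts of 714 and 668, and also that between the control arrays. The latter was 283, near the 256 and 227 of the other close pairs. The real change of control callus between the days is not known, so this does not exclude such noise as the source of the order. Delay as the source of most day 11 differences was argued against: the change of control callus from day 5 to day 11 was at least as large as the rest of the gap, in its direction, for 299 of 710 genes, or 42.1% (exact binomial 95% interval 38.4 to 45.8, over genes that are not independent). The noise of the day 11 control array enters both sides of that ratio and would raise the share. A control stage before day 5 was not measured, so a longer delay may account for more of the genes, and the pools give no measure of animal-to-animal spread.

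Agreement of the diabetes effect between days was higher at higher signal. The r was 0.416, 0.517, 0.539 and 0.661 in 4 equal bins of mean level, from dim to bright, while for the day effect in the 2 conditions it was 0.155, 0.169, 0.185 and 0.2.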
